A study of Meyerozyma caribbica with 6 samples.

How the data were processed

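RNA sequencing data of 6 libraries of Meyerozyma caribbica were used, 3 from control cultures and 3 from cultures with patulin, grouped by the titles and the treatment text of the labels. Libraries were made from total RNA with an Illumina TruSeq RNA kit, per the labels' protocols; strand use in counting is not given in the sources used here, so reads of a gene and of an antisense partner cannot be told apart. The labels are uncertain in places: the growth text names another yeast (Rhodotorula mucilaginosa), the extraction text speaks of retinas, and the submitters' processing notes list Bowtie 0.12.2 and a mouse genome build, which cannot have served for a yeast. The patulin dose is printed as the labels give it, and its unit could not be checked. The quantifier and the assembler are not given in the sources used here.

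Each library's deposited table holds expected counts (estimated read counts that need not be whole), TPM and FPKM for 5305 genes whose identifiers have the form of a de novo transcript assembly, per the file headers. The authors' TPM and FPKM values were not used for tests. An assembled gene can be a fragment, a fusion of neighbours or a variant of another gene. The median length of tested genes was 2966 bases. Genes matching aldA (TR3183|c0_g2), PFK2, HSP31 and STL1 had 11958, 11514, 12421 and 12685 bases, so their counts may include fused neighbours. Reads shared between similar assembled genes were divided by the authors' estimate. Values of the EBP1 matches, the IFF6 matches and other families are uncertain for that reason. A table of the authors' own comparison gives the p-value adjusted as a false discovery rate, the log2 fold change, FPKM and annotation for 234 genes, per the file headers. In it, 4 fold cells hold no number because a group is at 0, and 18 genes have no Swiss-Prot match. Its test is not named in the file. No genome was used, so no coordinates are given.

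Expected counts were rounded to whole numbers, which affected 18.2% to 19.4% of the values in a library. Genes were kept by filterByExpr of edgeR, leaving 3159 of 5305; the 2146 others held at most 0.178% of a library's counts, and 119 of them were at 0 in every library. Counts were scaled by TMM and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, 1 coefficient for patulin, 4 residual degrees of freedom before moderation) in R 4.3.3, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. Levels are TMM-scaled CPM (counts scaled to a common library size), log2 CPM used a prior count of 2, and the SE of a log2 fold change is its size divided by the square root of the F statistic, an approximation. A fold against a group at 0 used a floor of 3 counts per library, which covers counting error only. Replicates were compared by Pearson correlation across genes and by the chi-square of their counts over genes with at least 20 counts in the pair. Totals were 13488008 to 16172934 counts per library. The fitted biological coefficient of variation was 35.5% with all 6 libraries and 24.5% without control replicate 3.

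The test was run on simulated data for 3159 genes with the real means and library sizes and 50 genes changed at each fold. With the spread of all 6 libraries it recovered 30% of 2-fold, 82% of 4-fold, 98% of 8-fold and 100% of 16-fold changes, and with the spread found without control replicate 3 it recovered 70%, 90%, 100% and 100%. False calls numbered 8 and 6. The simulated genes varied independently, and no library stood apart as control replicate 3 does. These shares are therefore not the power of the real test. In the real edgeR fit, the gene matching AWA1 was 60.7-fold lower with an adjusted p of 0.0506.

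The gene lists (28, of which 6 had no named member), the tests, the rule for named genes and most alternatives were fixed before the data were examined. Lists were matched by symbol and by words in the protein name. Since only genes selected by the authors have names, no list test was run and only counts within the named genes are given. The rule took called genes with separated groups, a mean level at or above the median of tested genes and an informative name (the 10 largest rises and the 10 largest falls), and up to 2 called members per list. It gave TR649|c0_g1, TR98|c3_g1, TR3183|c0_g2, TR1720|c0_g1, TR1628|c0_g1, TR3671|c1_g1 and TR3067|c0_g1. Every other gene named was chosen after its values were seen.

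The alternatives were RLE scaling, scaling by library totals, no count filter, a stricter filter (at least 10 CPM in at least 3 libraries), DESeq2 1.42.0, limma 3.58.1 with a trend on log2 CPM, the replicate number as a block, a test against a 1.5-fold change (glmTreat), and leaving out each library in turn. Added after the data were seen were edgeR's exact test, limma-voom with a weight per library, and a fit without the 2 most abundant assembled genes.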

Results

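Transcript levels were measured by RNA sequencing in the yeast Meyerozyma caribbica (also called Pichia caribbica) grown for 24 h in NYDB broth at 28 °C and 180 rpm. The 3 control libraries came from cultures without patulin and the 3 patulin libraries from cultures to which patulin, a mycotoxin made by Penicillium moulds that reacts with thiol groups, had been added (20 mg/mL as the labels give it, whose unit could not be checked). The comparison addressed how the yeast's transcripts change under patulin stress. Total estimated counts were 14154910, 15002484 and 13488008 in control replicates 1, 2 and 3, and 14402469, 13755735 and 16172934 in patulin replicates 1, 2 and 3. They were spread over 5305 assembled genes, of which 3159 had enough counts to be tested. Only the 234 genes of the authors' deposited table carry names, which are best matches in Swiss-Prot to proteins of other fungi, so every named gene below is a match and not an annotated gene of this species.

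The 6 libraries did not fall into 2 even groups. On the first principal component, which held 69.2% of the variance, control replicates 1 and 2 lay at -50.2 and -46.8, and the patulin libraries at 33.4, 31.8 and 27.3, whereas control replicate 3 lay at 4.53. Control replicate 3 correlated across genes at r = 0.910 and 0.913 with the other controls and at 0.943, 0.944 and 0.953 with the patulin libraries. The other pairs within a group had r between 0.965 and 0.972. No pair of libraries agreed within sampling noise, the lowest chi-square per degree of freedom being 70.2 for control replicates 1 and 2. For most named genes the level of control replicate 3 is therefore given as a position. On this scale 0 is the mean of control replicates 1 and 2 and 1 is the mean of the patulin libraries. It is linear in CPM, so after a large fall a position near 1 can still be many-fold above the patulin level. For TR252|c0_g3, at 0.84, control replicate 3 had 480 CPM, beside 3436 and 2549 CPM in the other controls and 2.19 CPM with patulin. Over all tested genes in log2 CPM, control replicate 3 lay at 0.66 between the groups.

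**Figure D1:**
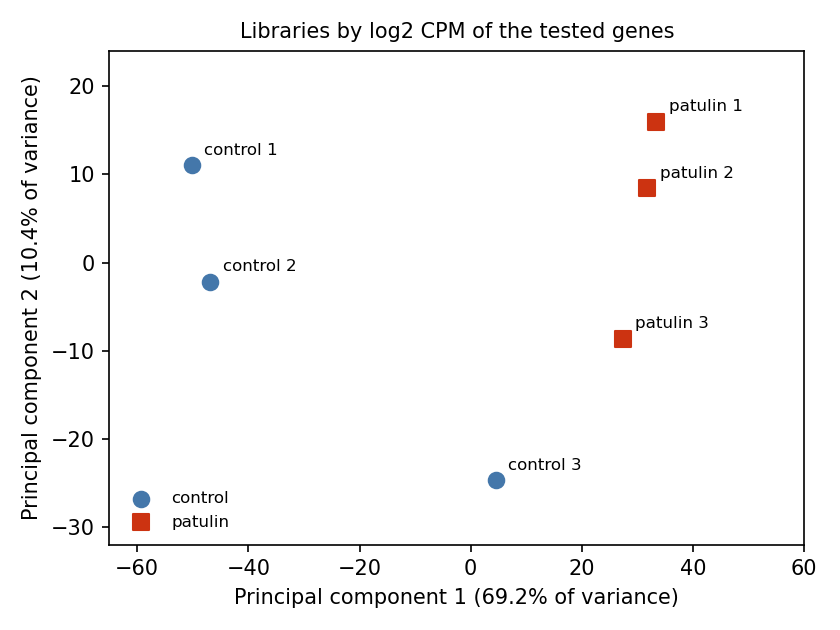
Scatter of the 6 libraries on the first 2 principal components (component scores without unit) of log2 CPM over the 3159 tested genes, with circles for control and squares for patulin libraries. Control replicates 1 and 2 lie at -50.2 and -46.8 on the first component, control replicate 3 at 4.53 and the patulin libraries between 27.3 and 33.4.

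Genes matching NADPH dehydrogenases of the old yellow enzyme family were higher with patulin. These flavoenzymes reduce the carbon double bonds of unsaturated aldehydes and ketones. The authors' deposited table listed 6 assembled genes whose best match is EBP1, the estrogen-binding family member of Candida albicans, and all 3 patulin libraries lay above all 3 control libraries for each of the 6. By the closest entry in the nr protein database, the 6 stand for 4 distinct proteins. TR3671|c1_g1 rose from 0.529 ± 0.139 to 7.43 ± 0.915 CPM (mean ± SD, n = 3 and 3), which is 13.9-fold (log2 fold change 3.80, SE 0.33; adjusted p = 0.0479, edgeR quasi-likelihood test). TR3067|c0_g1 rose from 3.87 ± 1.42 to 62.0 ± 21.9 CPM, 16.1-fold (log2 fold change 4.0, SE 0.40; adjusted p = 0.0479), and TR3671|c0_g1 rose from 2.61 ± 1.30 to 37.9 ± 11.1 CPM (log2 fold change 3.86, SE 0.46; adjusted p = 0.0479). The other three did not pass the threshold in edgeR and did in DESeq2: the log2 fold changes were 2.69 for TR3436|c0_g1 (adjusted p = 0.0506), 2.44 for TR1694|c0_g1 (adjusted p = 0.0664) and 1.79 for TR3671|c0_g2 (adjusted p = 0.0952, and 2.63 without control replicate 3). On the linear scale control replicate 3 lay close to the other controls for 5 of the 6, at positions of 0.0324, 0.0399, 0.055, 0.131 and 0.187, and at 0.471 for TR3671|c0_g2. It was nevertheless the highest control for each of the 6, for example at 22.74 CPM beside 11.6 and 8.699 CPM for TR1694|c0_g1. The list of short-chain, aldo-keto and related reductases held 7 named genes, of which 3 rose over all genes tested in edgeR, and 6 were higher and 1 lower adjusted over the list alone or by DESeq2 over all genes. Here and below, a list alone spans only genes the authors had selected as changed on these libraries, so passing that adjustment adds no support. The seventh, matching the methylglyoxal reductase GRP2 (TR3661|c0_g2), was at 181 ± 110 CPM in controls and 12.9 ± 5.82 CPM with patulin (adjusted p = 0.0637).

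A further 3 genes rose. TR649|c0_g1, whose best match is condensin subunit 1, a part of the complex that compacts chromosomes, rose from 80.2 ± 21.6 to 769 ± 267 CPM, or 9.59-fold (log2 fold change 3.26, SE 0.37; adjusted p = 0.0479). TR3472|c1_g2, matching the membrane protein SNG1 that gives resistance to nitrosoguanidine, rose 3.98-fold from 20.4 ± 3.44 to 81.1 ± 23.8 CPM (log2 fold change 1.99, SE 0.25; adjusted p = 0.049). TR141|c0_g1, matching the S-adenosylmethionine-dependent methyltransferase CRG1, had 0 counts in all 3 controls and 55.8 ± 20.8 CPM with patulin, so it was at least 284-fold higher against a floor of 3 counts per library (adjusted p = 0.0479). Control replicate 3 lay at -0.0552, 0.0822 and 0 for these genes.

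The 3 drug efflux genes, of which 2 are sibling assemblies of 1 TPO1 protein, were all higher in the patulin libraries, but none passed the threshold over all genes tested in edgeR, whereas all 3 did adjusted over the list alone or by DESeq2 over all genes. The gene matching multidrug resistance protein 1 (TR936|c1_g1) was at 2.67 ± 2.07 CPM in controls and 94.6 ± 97.0 CPM with patulin (log2 fold change 5.16, SE 1.10; adjusted p = 0.0711). Its patulin libraries were at 17.95, 62.28 and 203.7 CPM, the log2 fold change was 3.92 without patulin replicate 3 and 5.94 without control replicate 3, and the false discovery rate in the authors' deposited table was 0.101. The polyamine transporter TPO1 (TR142|c0_g1) was at 199 ± 116 and 840 ± 67.6 CPM (adjusted p = 0.067). Control replicate 3 lay at 0.0385 and 0.283 for these 2 genes.

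Of the 7 named genes for iron and copper uptake, 6 were higher and 1 lower in the patulin libraries. None was called over all genes tested by edgeR, and 3 were higher and 1 lower adjusted over the list alone or by DESeq2 over all genes. The siderophore transporter ARN1 (TR2795|c0_g1) was at 9.01 ± 7.32 and 58.4 ± 20.7 CPM (log2 fold change 2.70, adjusted p = 0.0723, and 3.54 and 0.00182 without control replicate 3), and the copper-transporting ATPase CCC2 (TR2248|c0_g1) at 82.2 ± 12.2 and 169 ± 15.7 CPM (adjusted p = 0.0506), with control replicate 3 at 0.234 and 0.225. In the siderophore transporter mirB (TR1757|c0_g1) and the reductase FRE7 (TR3135|c0_g1), control replicate 3 had almost the patulin level, at positions of 0.808 and 0.79. Their adjusted p-values were 0.295 and 0.27 with all 6 libraries, and 0.000259 and 0.000269 without control replicate 3.

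All 11 named members of the cell wall list, which stand for 8 distinct nr entries, lay lower in all 3 patulin libraries than in any control, 1 fell over all genes tested in edgeR and 10 were lower adjusted over the list alone or by DESeq2 over all genes. The chitinase-like gene TR1628|c0_g1 fell from 2772 ± 2100 to 8.65 ± 2.41 CPM, 320.0-fold lower (log2 fold change -8.32, SE 0.96; adjusted p = 0.0479). The cell wall proteins AWA1 (TR1523|c0_g1) and IFF6 (TR98|c1_g1) had log2 fold changes of -5.92 (SE 0.85) and -4.45 (SE 0.68), each with an adjusted p of 0.0506. Levels of AWA1 in control replicates 1, 2 and 3 were uneven, at 3435, 2059 and 426.3 CPM. Surface proteins outside the list went both ways: the cell-surface glycoprotein DFI1 (TR2062|c1_g1) and the GPI-anchored protein PGA52 (TR1063|c0_g1) had log2 fold changes of 1.89 and 1.08 (adjusted p = 0.0747 and 0.0701 in edgeR, under 0.05 in DESeq2, and log2 2.56 for DFI1 without control replicate 3), while others were lower. Control replicate 3 lay at 0.844, 0.855 and 0.707 for the chitinase-like gene, AWA1 and IFF6. Its level of the chitinase-like gene was 609 CPM, beside 4802 and 2905 CPM in the other controls and at most 11.0 CPM in a patulin library.

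All 7 named alcohol and aldehyde dehydrogenases (6 distinct nr entries), which oxidise or form aldehydes, were lower in every patulin library than in any control. Among them, the gene matching aldA (TR3183|c0_g2) fell from 1449 ± 293 to 469 ± 33.4 CPM, 3.09-fold lower (log2 fold change -1.63, SE 0.20, adjusted p = 0.049 in edgeR). This assembled gene has 11958 bases, so its fall may not be that of aldA alone. All 7 were lower adjusted over the list alone or by DESeq2 over all genes. The fatty aldehyde dehydrogenase HFD1 (TR2600|c0_g1) was at 892 ± 566 CPM in controls and 35.1 ± 4.54 CPM with patulin (log2 fold change -4.67, SE 0.68; adjusted p = 0.0506). The NADP-dependent alcohol dehydrogenase ADH6 (TR1938|c0_g1) was at 196 ± 125 and 23.0 ± 22.7 CPM (adjusted p = 0.0931). Control replicate 3 lay at 0.421 for aldA, 0.828 for HFD1 and 0.866 for ADH6.

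The other genes that fell were of mixed kinds. TR1628|c1_g1, whose Swiss-Prot match is a globin-like protein, has the same nr entry as the chitinase-like TR1628|c0_g1, so the pair is not shown to be 2 genes. It fell from 1337 ± 990.5 to 5.26 ± 0.593 CPM (log2 fold change -7.99, SE 0.91; adjusted p = 0.0479). The gene matching SEC31, a coat protein of vesicles that leave the endoplasmic reticulum (TR1720|c0_g1), fell from 283 ± 206 to 1.99 ± 0.796 CPM (log2 fold change -7.16, SE 0.89; adjusted p = 0.049). Its match is to SEC31 of a distant fungus, and the gene matching SEC31 of the close relative Meyerozyma guilliermondii (TR164|c0_g1) was at 55.02 ± 12.27 and 25.97 ± 9.542 CPM (log2 fold change -1.08; adjusted p = 0.0859). FMP40 (TR98|c3_g1), a mitochondrial protein, fell from 205 ± 32.4 to 86.7 ± 5.77 CPM (log2 fold change -1.24, SE 0.15; adjusted p = 0.0479). A gene without a named match (TR252|c0_g3) fell from 2155 ± 1517 to 2.19 ± 0.703 CPM (log2 fold change -9.94, SE 1.01; adjusted p = 0.0479), and a pair of unannotated genes with identical counts (TR1098|c0_g1 and a sibling) fell from 123 ± 11.9 to 63.9 ± 4.0 CPM each. Control replicate 3 lay at 0.846, 0.826, 0.525, 0.394, 0.84 and 0.226 for these genes, in the order given.

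The named members of the glutathione and peroxide defence lists were lower in the patulin libraries without passing the threshold over all genes in edgeR, whereas DESeq2 called all of them. Catalase T (CTT1, TR1434|c1_g1), which breaks down hydrogen peroxide, was at 5483 ± 2314 CPM in controls and 1298 ± 656 CPM with patulin (adjusted p = 0.0747). Glutathione S-transferase 1 (GTT1, TR2954|c0_g1) was at 191 ± 119 and 18.2 ± 8.65 CPM (adjusted p = 0.07), and a mitochondrial glutaredoxin (TR345|c0_g1) at 1165 ± 381 and 458 ± 24.0 CPM (adjusted p = 0.0706). All 3 members of the glutathione list were lower adjusted over the list alone, as was the single member of the peroxide list; the third glutathione member, HSP31, is a glutathione-independent glyoxalase. Control replicate 3 lay at 0.722, 0.846 and 0.708 for CTT1, GTT1 and the glutaredoxin. A putative heme-binding peroxidase outside these lists (TR3290|c1_g2) went the other way, at 242.8 ± 248 CPM in controls and 933.8 ± 16.95 CPM with patulin (log2 fold change 1.94, adjusted p = 0.123 in edgeR and 0.0212 in DESeq2, and 3.18 and 0.000228 without control replicate 3, which lay at 0.515). Both matches to the thiol-specific monooxygenase fmo1 (TR1107|c0_g1 and TR1107|c0_g2) were higher too, with log2 fold changes of 2.66 and 4.12 (adjusted p = 0.231 and 0.116 in edgeR). The match to the oxidoreductin ERO1 (TR12|c0_g1) had 1.55 (adjusted p = 0.166 in edgeR).

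**Figure D2:**
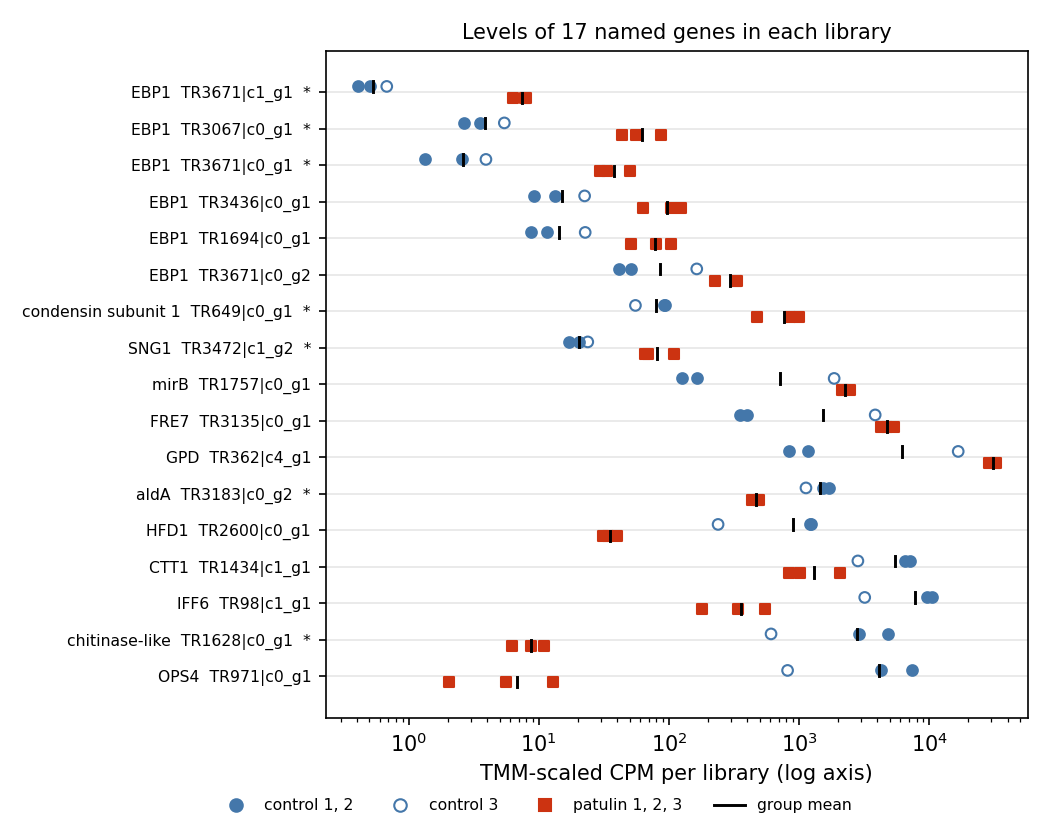
Levels of 17 named genes in each of the 6 libraries, as TMM-scaled CPM on a log axis, with circles for controls (open for control replicate 3), squares for patulin, black ticks for the mean of each group (n = 3) and an asterisk at each gene with an adjusted p under 0.05. Control replicate 3 is the highest control for each EBP1 match but lies nearer the other controls than the patulin libraries for most of them. It stays with the other controls for condensin subunit 1 (position -0.0552) and lies near the patulin libraries for mirB (0.808) and FRE7 (0.79).

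Over all genes, 6 rose and 8 fell at an adjusted p under 0.05 (edgeR quasi-likelihood test), 12 of them at least 2-fold. The adjustment gave tied values. The lowest, 0.0479, was shared by genes with an unadjusted p from 2.55e-05 to 0.000167 in the same test, so it does not rank them. Several uncalled genes shared 0.0506, so the line between called and uncalled genes is not sharp. At an unadjusted p under 0.05 there were 1075 genes, and for 40.5% of the tested genes all 3 patulin libraries lay on one side of all 3 controls (638 higher and 640 lower). A gene with its libraries in random order would do so with a probability of 10%. Genes vary together in these libraries, so the excess is not a test against chance. The number of calls rested on single libraries. Without control replicate 3, 834 genes were higher and 885 lower, including all 14 genes called with 6 libraries, and leaving out any of the other 5 libraries left 0 calls (590 to 847 genes at an unadjusted p under 0.05). DESeq2 called 297 higher and 546 lower on all 6 libraries. Higher genes made up 42.9% of the calls with TMM scaling, 22% with RLE scaling, 24.4% without the 2 most abundant assembled genes and 6.84% with scaling by library totals. The median log2 fold change of the tested genes was 0.06 with TMM scaling and -0.17 with library totals.

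The authors' deposited table listed 84 genes as up and 150 as down, 232 of the 234 with a false discovery rate under 0.05. All 234 had the same direction in the edgeR fit. The fit called 12 of them with all 6 libraries and 226 without control replicate 3, and DESeq2 called 208. In all 3 patulin libraries against all 3 controls, 81 of the 84 were higher and 149 of the 150 lower. For TR3067|c0_g1 the authors' deposited table gave a log2 fold change of 3.97, beside 4.0 in the edgeR fit. As the named genes are those the authors selected on these same libraries, the list counts above are not independent evidence of a direction, and no list was tested against the rest of the genes. That selection also made passing the adjustment over a list alone more likely, so those counts are not evidence of change. The labels do not say whether replicates were separate cultures, so the p-values measure the spread between these libraries, which may be technical.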

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

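The exact test, the library weights, the fit without the 2 most abundant genes and the overlap counts other than the one by fold size were chosen after the data were seen. With 6 genes higher, 8 lower, 12 changed at least 2-fold and 12 shared with the authors' deposited table as the starting point, in that order, RLE scaling gave 9, 32, 33 and 32 genes, scaling by library totals 16, 218, 222 and 149, no filter 10, 40, 45 and 44, the stricter filter 12, 35, 35 and 35, DESeq2 297, 546, 350 and 208, and limma with a trend 10, 28, 34 and 33. The edgeR exact test gave 149, 316, 311 and 199, limma-voom with library weights 1070, 950, 792 and 232, and the fit without the 2 most abundant genes 10, 31, 34 and 33. The test against a 1.5-fold change called 0 genes of at least 2-fold, where 12 passed the plain edgeR test and 350 DESeq2. Leaving out 1 library gave 0 to 834 genes higher, 0 to 885 lower, 0 to 757 changed at least 2-fold and 0 to 226 shared; the highest values came without control replicate 3 and the 0s without each of the other 5 libraries, where 590 to 847 genes had an unadjusted p under 0.05. Apart from the test against a 1.5-fold change, the 14 genes were called again in each of these settings with 3 exceptions. These were the stricter filter (13), the fits that left out a library other than control replicate 3 (0) and the replicate block (0). In the test against a 1.5-fold change only calls of at least 2-fold were counted. The TR1098 pair, which changed less than that, was therefore not assessed there. The cause of these shifts was not tested. For 54 of the genes named in the text, 863 values under 16 settings all had the same direction. Of these values, 566 had the same call, 213 gained it and 84 lost it. The genes were named for their difference on the same libraries, so the shared direction was largely fixed in advance.

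With the replicate number as a block there were 0 genes higher, 0 lower, 0 changed at least 2-fold and 0 shared (lowest adjusted p = 0.2; 767 genes at an unadjusted p under 0.05). The residuals of same-numbered libraries correlated at 0.0704, -0.0341 and -0.0522, and control replicates 2 and 3 correlated more with another number, so the numbers were not taken to pair the libraries. Alternatives for normalized values (pseudocounts, quantile or median scaling) and all alternatives for the list tests were not run, since the files hold counts and no list test was made. Depth, at 13488008 to 16172934 counts, limits the genes near the floor, such as TR3671|c1_g1 at 0.529 CPM in controls.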

Other observations

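Further named genes, none of them called by edgeR with all 6 libraries, follow by list, and DESeq2 called many of them on the same libraries. The name pattern fixed for cytosolic ribosomal proteins matched 5 genes, of which 4 were higher and 1 lower in all 3 patulin libraries than in any control, and all 5 were called without control replicate 3. With all 6 libraries only 1 higher and 1 lower gene passed adjusted over the list alone, and the same numbers by DESeq2 over all genes. RPL10 (TR1758|c0_g1) was at 527 ± 199 CPM in controls and 1261 ± 109 CPM with patulin (adjusted p = 0.0714, edgeR quasi-likelihood test, n = 3 and 3), with control replicate 3 at a position of 0.406. The lower gene, TR131|c0_g3 (log2 fold change -1.10), matches RPL3 in Swiss-Prot but another, hypothetical protein in nr, whereas TR131|c0_g2 matches RPL3 in both (1.53, adjusted p = 0.215, with control replicate 3 at 0.759, and 2.96 without it). The acidic ribosomal proteins RPP1B (TR2019|c0_g1) and RPP1A (TR502|c0_g1), which the pattern missed, had log2 fold changes of 1.46 (adjusted p = 0.0506) and 1.18 (adjusted p = 0.108). The 2 glycolysis genes went opposite ways. The glyceraldehyde-3-phosphate dehydrogenase match GPD (TR362|c4_g1) was at 1168 and 831 CPM in control replicates 1 and 2, 16680 CPM in control replicate 3 and 31020 ± 2056 CPM with patulin (log2 fold change 2.32, and 4.90 without control replicate 3), and the phosphofructokinase PFK2 (TR3701|c0_g2) at 4996 ± 2173 CPM in controls and 1691 ± 345 CPM with patulin (control replicate 3 at 0.821). ATP4 (TR1827|c0_g1) and COX9 (TR3193|c0_g1), parts of the mitochondrial ATP synthase and cytochrome c oxidase, had log2 fold changes of 1.07 and 1.12 (1.71 for COX9 without control replicate 3), with control replicate 3 at 0.518 and 0.708. The flavohemoprotein YHB1 (TR2800|c0_g2), which detoxifies nitric oxide, and a glycerol-1-phosphate phosphohydrolase (TR1068|c0_g1), both on no list, had log2 fold changes of 2.02 and 2.28 (adjusted p = 0.249 and 0.239) and of 4.49 and 5.18 without control replicate 3, which lay at 0.64 and 0.552.

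The 3 sugar transporters, STL1 (TR2983|c0_g1), LAC12 (TR431|c0_g1) and rco-3 (TR919|c0_g1), had log2 fold changes of -1.23, -3.13 and -4.55, with control replicate 3 at 0.65, 0.882 and 0.84. None was called by edgeR and all 3 by DESeq2 with all 6 libraries, and 3 of 3 were lower adjusted over the list alone. LAC12 was at 3.306, 2.947 and 16.48 CPM in patulin replicates 1, 2 and 3, so the size of its fall depends on replicate 3. Of 5 permeases for amino acids and other nitrogen sources, 4 were lower adjusted over the list alone, among them DIP5 (TR1787|c0_g1, -1.68, with control replicate 3 at 0.719). The cytochrome P450 alkane hydroxylases CYP52A13 (TR1293|c0_g1) and CYP52A12 (TR3074|c0_g1) had log2 fold changes of -3.48 and -3.74, with control replicate 3 at 0.839 and 0.856. Both matches to the opaque-phase protein OPS4 (TR971|c0_g1 and TR1019|c0_g1) went from 4144 ± 3273 and 4202 ± 3328 CPM to 6.82 ± 5.51 and 7.17 ± 5.44 CPM (adjusted p = 0.0506 each), with control replicate 3 at 0.861 and 0.845. These genes were selected by the authors on the same libraries.

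The tests in the rest of this part were chosen after the results were seen, and those for a wrong label and a mixture replaced earlier forms whose values are given beside them. Control replicate 3 lies between the groups: over 744 genes called without it and changed at least 2-fold (of 757, leaving out 13 not tested with all 6 libraries), its median position was 0.772 for 404 rising and 0.817 for 340 falling genes. For a wrong label on a patulin library, genes were called from control replicates 1 and 2 and 2 patulin libraries. Control replicate 3 lay more than 2-fold outside those patulin libraries, on the control side, for 79, 80 and 121 genes. The held-out patulin library did so for 24, 18 and 38, a ratio of at least 3.18 that is little above the bound of 3 (earlier form: 73 of the 744 genes against at most 21). The bound was set after the results were seen. The values argue weakly against a mislabelled library like the other patulin libraries, and do not cover a mislabelled patulin library from another batch. The length of the assembled gene accounted for 2.19% of the variance of the shift, which argues against a bias by that length. Assembled genes can be fusions or fragments, so a bias by the length of the true transcript was not tested. A mixture of control and patulin RNA cannot be told apart from the other causes left. At a patulin share of 80%, 83.9% of the 744 genes lay within 1.2-fold of the mixed range. That range runs from the mixed lowest to the mixed highest replicate levels, so it can be far wider than 1.2-fold around a mean. At that share, 13 rising genes lay more than 3-fold under the mixed level, against at most 6 for a patulin library. CRG1 had 0 counts where the share would give 591. There were 6 control-only genes (0 in the patulin libraries, at least 100 counts in control replicates 1 and 2). Of these, 3 had 0 in control replicate 3 where 357, 31 and 3440 would be expected. The other 3 had 131, 171 and 716 where 193, 240 and 529 would be expected. The earlier form of this test was a median position of 0.131 over 9 reductase and efflux genes chosen for it. A difference in culture state or an unlabelled batch also remains open, and no biological explanation was tested.

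A second pattern is that the 6 EBP1 matches are higher with patulin while control replicate 3 has a median position of 0.093 on the linear scale. It is still the highest control for each of the 6. These genes were noticed through calls and a table that use control replicate 3 as a control, which favours low positions: of the 84 genes the authors' deposited table lists as up, 20 had a position under 0.25 and the median was 0.495. Over the 404 rising genes called without control replicate 3, which are free of that choice, 6.68% lay under 0.25 and the median was 0.772, but the EBP1 matches, though called there too, were not picked from that set. Whether the EBP1 matches follow the shift that sets control replicate 3 apart therefore cannot be told from these libraries, and TR3671|c0_g2 lay at 0.471.

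Other splits of the 6 libraries into 3 and 3 were too few (10) for a share under 0.05. The real split was the only 1 with as many genes higher (6), lower (8) or changed at least 2-fold (12), and the highest number in any other split was 0 for each.

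An assembled gene of 4019 bases, not tested because it was detected in 2 libraries, had 19327 and 17744 counts in control replicates 1 and 2 and 0 in control replicate 3 and the 3 patulin libraries. A count of 0 beside at least 1000 counts in the rest of the group (for controls, in replicates 1 and 2 only) occurred for this gene and 1 other in control replicate 3 and in no other library, whereas beside at least 100 counts it occurred for 4 genes in control replicate 3 and 1 to 10 in each other library. Some siblings of the 3 control-only genes at 0 in control replicate 3 had higher counts there than in the other controls, and whether reads moved between siblings could not be checked without sequences. The 2 most abundant assembled genes, neither named, took 5.62%, 3.95% and 4.49% of the counts in the control libraries and 13.1%, 4.22% and 24.6% in the patulin libraries.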
